A study of Mus musculus with 6 samples.

How the data were processed

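Total RNA of Ba/F3 cells was sequenced, per the labels, from 3 replicates that carried hCALR and 3 that carried hCALR-del52. Groups were taken from the sample titles. Nothing in the labels says whether the replicates are separate cultures or separate transductions, so that p-values measure only the spread between these samples, which may be technical.

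Per the file headers and the submitters' processing notes, the authors used Bowtie2 2.1.0, TopHat2 2.0.9 and Cuffdiff 2.1.1 with the mm10 genome and Ensembl genes. The authors' deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) as 1 value per group. It also gives the log2 fold change of hCALR-del52 over hCALR, which the authors computed from the FPKM. The p-value and the Benjamini-Hochberg q-value are the authors' own. The rank, a score by p-value and fold change, was also deposited by the authors and was used here only to check the table. Per the file headers, genes with low expression and highly variable genes were removed. Ranks ran to 15521 over 12615 rows, and 2906 ranks have no row, so that some genes with a rank were not analysed here. The larger of both FPKM values was at least 1.01 in every row.

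Coordinates are those of the table, in mm10. Of 10962 rows with a single identifier that the GENCODE mouse annotation of the same build holds, 40.9% had its gene start after 1 was added and 1.07% without. The starts therefore count from 0, and 1 was added to print them. A locus can cover several overlapping genes, and 480 rows carry several identifiers. Gene types come from that annotation. A symbol was missing in 2335 rows, and 188 symbols stand on more than 1 row, of which the row with the highest mean FPKM was used.

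Since the table holds no value per replicate, no test over replicates was made. Called genes are those with the authors' q under 0.05, as set before the data were examined, and they were counted by direction. In 18 rows, 1 of them called, the deposited log2 fold change differed from the log2 of the FPKM ratio by over 0.001. The smallest q in the authors' deposited table is 0.00161, while Benjamini-Hochberg adjustment over all p-values of the table gives 0.00548 as its smallest value. Which tests the deposited q covers is not given in the sources used here. It is smaller at the same p, so it did not come from adjustment over exactly these rows. Rows removed from the table may have been part of it. A call that ended when the adjustment covered all rows therefore depends on which rows the table holds.

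The log2 ratio computed here is log2((FPKM hCALR-del52 + 1)/(FPKM hCALR + 1)), which understates the change of low genes. Folds are plain ratios of both FPKM values. The 26 gene lists were fixed before the data were examined and include markers of other blood cells and of stroma. They were compared over 9667 genes with a symbol, a single identifier and at least 1 FPKM in at least 1 group. The share of called genes in each list was tested by Fisher's exact test (two-sided), separately for higher and lower calls, with Benjamini-Hochberg adjustment over 52 tests. Genes are not independent, so these p-values describe an excess among genes, not replicate error. The median log2 ratio of each list was set against 10000 random lists matched on mean FPKM in 20 bins, and lists under the 2.5th or above the 97.5th percentile are given as outside the range. Calls adjusted over the list alone use the authors' p-values of its members. Every called row had a p of at most 0.00275. In short lists, or in lists with several calls, a called member therefore passes this adjustment by construction, which is no second support for its call.

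Both list steps were tested on simulated data over the 9667 genes in 20 runs. A list shifted by 0.5 on the log2 scale fell outside the range in 100% of runs and one shifted by 0.2 in 80% of runs, while 5.47% of other lists did. A list with planted calls was found in 100% of runs by Fisher's exact test, which called 0% of the others. Calls were planted in a large share of the list, and simulated genes were independent of each other. These rates therefore do not cover lists with few calls or lists whose members vary together.

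Genes are named by a rule set before the data were examined. It takes the 12 called genes with the highest and the 12 with the lowest log2 ratio that have a symbol other than a clone or model name. It adds up to 4 called members of each list with the largest absolute ratio, and a fixed set of genes whatever their values, among them Calr, Il3ra, Csf2rb, Csf2rb2, Jak2, Stat5a, Stat5b, Cish, Pim1, Hspa5 and Ddit3. Some items that the rule names are not reported here, while counts and list tests include all genes. Other list members, and the genes of the closing section, were named after their values were seen.

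Alternatives were a q threshold of 0.01, a minimum absolute log2 fold change of 1, a minimum of 1 FPKM with and without a new adjustment, Bonferroni adjustment, a minimum of 5 FPKM or none for the lists, a pseudocount of 0.1, and ratios centred on the median of all genes. Added after the data were seen were rows of single genes with a symbol, lists without chromosome 17, and the list tests with calls adjusted over all rows. For the counts, adjustment over all rows equals the planned adjustment above 1 FPKM, since every row passes that minimum. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.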

Results

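The series compared mouse Ba/F3 cells, a pro-B cell line that depends on interleukin-3 (IL-3), that carried human calreticulin (hCALR) with Ba/F3 cells that carried hCALR with the type 1 mutation (hCALR-del52). CALR is a chaperone of the endoplasmic reticulum, and the type 1 mutation is a deletion found in myeloproliferative neoplasms. Both lines were transduced with a retroviral vector and cultured with IL-3 at 1 ng/ml. RNA was sequenced from 3 replicates of each group, 6 samples in all. The deposited table gave 1 FPKM value per group for each of 12615 rows, with the authors' Cuffdiff test of hCALR-del52 against hCALR. No value per replicate was used here, so that the group values below carry no SD, and the depth of the samples is unknown. Every FPKM below is the authors' group value, and every fold is the ratio of both group values.

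The endogenous mouse Calr gene (ENSMUSG00000003814, chromosome 8, 84841850 to 84846934, mm10, protein coding) was at 1180 FPKM in hCALR cells and 906 FPKM in hCALR-del52 cells. The authors' deposited table gave this difference a log2 fold change of -0.38 with p = 0.364, so it was not called. Reads of the human transgene may map to this row in part, so that it does not measure the endogenous gene alone.

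The comparison asked which genes differ between cells with mutant and with unmutated CALR while IL-3 is present. Construct and transduced line go together in this design, so that a difference between the groups need not be an effect of the mutation. The beta-globin gene Hbb-b1 (chromosome 7, 103826534 to 103828096) rose from 4.33 to 422 FPKM. In the authors' deposited table its log2 fold change was 6.61 with q = 0.00161, the smallest q in the table. The 115 rows with the smallest p share this q, so that it does not rank Hbb-b1 above them. Tnni1, the slow skeletal muscle troponin I gene (chromosome 1, 135783065 to 135810989), rose from 0.876 to 90.7 FPKM. Among the genes that fell, P2ry1, a receptor for extracellular ADP, went from 10.2 to 0.226 FPKM, and Emr1, which encodes the macrophage marker F4/80, from 34.9 to 2.20 FPKM. Jak1, a kinase bound to cytokine receptors, fell from 518 to 141 FPKM.

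At the authors' q under 0.05, 232 of 12615 rows were called, 110 higher and 122 lower in hCALR-del52 cells, and 209 of them differed by at least 2-fold in the authors' deposited table. A gene symbol was given for 183 of the called rows. Most genes left in the table lay close to equality: over 9667 genes with a symbol, 93.0% had a log2 ratio within 0.5 of 0, and the median log2 ratio was -0.01. Genes with low expression and highly variable genes had been removed, so that neither this share nor the count of calls describes all genes. Pearson's r across these genes was 0.982 on the log2(FPKM + 1) scale. Genes are not independent replicates, and no p-value belongs to this r. Benjamini-Hochberg adjustment repeated over the p-values of all rows left 172 calls, 80 higher and 92 lower. The authors' q was not adjusted over exactly these rows, so that calls ended by the repeated adjustment depend on the rows left in the table.

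**Figure D1:**
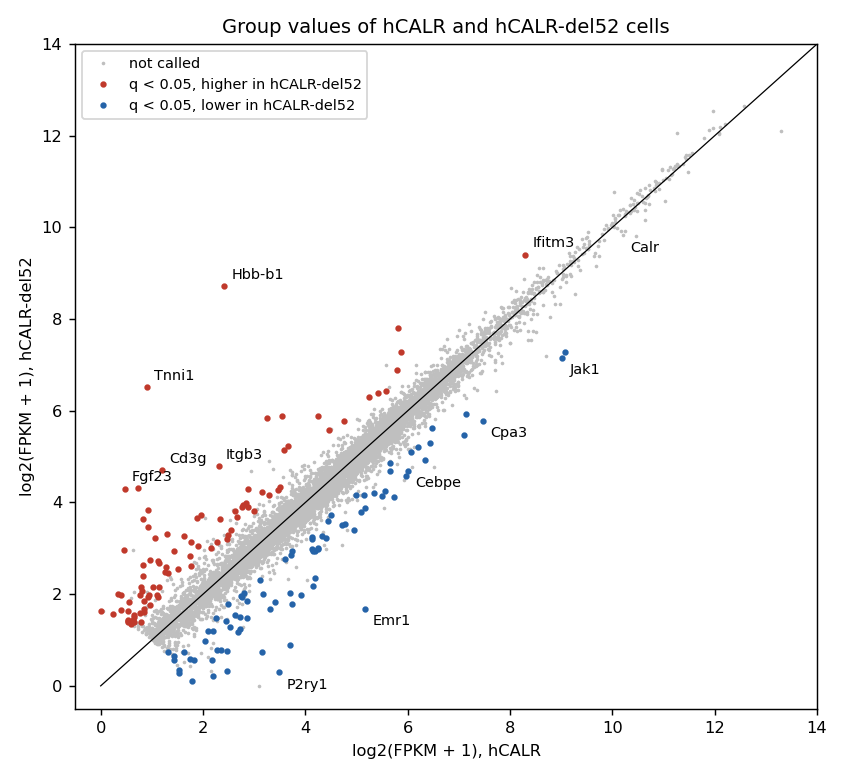
Group values of 9667 genes as log2(FPKM + 1), with hCALR cells on the x axis and hCALR-del52 cells on the y axis. Each point is a gene, red and blue points are genes with the authors' q under 0.05, and the line marks equality. Hbb-b1 lies at 4.33 FPKM on the x axis and 422 FPKM on the y axis, and genes not reported here are not drawn.

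Other genes among the 12 with the highest ratios included further blood cell genes. The embryonic globin Hbb-bh1 rose from 0.648 to 18.8 FPKM, Hbb-b2 from 0.899 to 13.3 FPKM and the embryonic globin Hbb-y from 0.373 to 6.81 FPKM. Cd3g, a chain of the T cell receptor complex, rose from 1.29 to 25.1 FPKM, Grap2, an adaptor of T cell signalling, from 0.779 to 11.5 FPKM and the granzyme gene Gzmc from 0.894 to 10.1 FPKM. Fgf23, a phosphate-regulating hormone gene, rose from 0.386 to 18.7 FPKM, and the transcription factor gene Plag1 rose 6.60-fold to 56.4 FPKM. The call of Hbb-bh1 ended when the adjustment covered all rows, with an adjusted p of 0.0538. Folds of genes under 1 FPKM in hCALR cells rest on values close to 0.

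Of the 12 genes with the lowest ratios, 5 were T cell receptor variable segments. Trbv13-2, in a row that also carries the identifier of an overlapping gene (chromosome 6, 41118256 to 41122772), fell from 433 to 28.4 FPKM. Trbv17, in a row with 2 identifiers, fell from 4.21 to 0.127 FPKM, Trbv15 from 4.51 to 0.252 FPKM, Trbv26 from 3.59 to 0.160 FPKM and Trdv4 from 16.8 to 3.50 FPKM. A second row of Trbv17, with 1 identifier, was at 1.83 and 0.370 FPKM and a second row of Trbv26 at 2.89 and 0.0940 FPKM, and neither was called. The call of Trbv15 ended when the adjustment covered all rows, with an adjusted p of 0.134. A T cell receptor alpha segment went the other way: Trav18, named here after its value was seen, rose from 0.309 to 2.17 FPKM. The other genes were Serpinb1a, a protease inhibitor gene, from 12.1 to 0.860 FPKM, Nhsl2 from 7.91 to 0.658 FPKM, Serpini1, which encodes neuroserpin, from 12.4 to 2.43 FPKM and Fam20a from 14.1 to 2.93 FPKM, besides P2ry1, Emr1 and Jak1.

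Of 19 measured erythroid markers, 8 rose, none fell and 11 were not called. Besides Hbb-b1, Hbb-b2 and Hbb-y, they included Hba-a1, from 55.4 to 222 FPKM, Hba-a2, Hemgn, from 7.83 to 17.7 FPKM, and Rhd. All 8 were also called with the p-values adjusted over the list alone, which the small p-values of called rows ensure here. When the adjustment covered all rows, 6 were called, while Rhd had an adjusted p of 0.0599 and Hba-a2 of 0.0757. Outside the list 0.881% of 9648 genes were called higher, and Fisher's exact test (two-sided) gave an adjusted p = 1.95e-10 over the 52 list tests. Among the members that were not called, Klf1, an erythroid transcription factor gene, was at 61.8 and 77.4 FPKM, and Epb4.2, a red cell membrane gene, at 15.9 and 12.6 FPKM in hCALR and hCALR-del52 cells. The globin copies resemble each other, and reads could be split between them, so that the value of a single copy is uncertain.

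Of 20 measured interferon-stimulated genes, 5 rose, none fell and 15 were not called. The same 5 were called with the p-values adjusted over the list alone. Oas2, a sensor of double-stranded RNA, rose from 2.67 to 11.6 FPKM, Ifit1 from 1.40 to 4.61 FPKM, Oasl1 from 5.77 to 13.9 FPKM and Ifitm3, an inhibitor of virus entry, from 312 to 677 FPKM. Oasl2 was the other. Outside the list 0.912% of 9647 genes were called higher, and Fisher's exact test (two-sided) for the excess of higher calls gave an adjusted p = 1.77e-05. The call of Oasl1 ended when the adjustment covered all rows, with an adjusted p of 0.0624. Outside the list, the interferon-inducible gene Ifi27l2a, named after its value was seen, went the other way. It fell from 5.62 to 1.84 FPKM, a call that also ended when the adjustment covered all rows, with an adjusted p of 0.0641.

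Of 9 measured granulocyte and monocyte markers, 5 fell and 1 rose, and 7 were called with the p-values adjusted over the list alone, 5 lower and 2 higher. Emr1 fell 15.9-fold. The granule gene Ngp fell from 5.61 to 1.37 FPKM, the calprotectin gene S100a8 from 8.86 to 2.22 FPKM, and Cebpe, a transcription factor of granulocyte maturation, from 62.9 to 24.7 FPKM. S100a9 fell as well, while Lyz2, which encodes lysozyme, rose from 3.48 to 6.98 FPKM, a call that ended when the adjustment covered all rows, with an adjusted p of 0.118. Mpo, which encodes myeloperoxidase, was at 3.60 and 6.93 FPKM and was called higher over the list alone. Fisher's exact test (two-sided) for the excess of lower calls gave an adjusted p = 1.32e-07. Of 12 mast cell and basophil markers, the protease genes Cpa3, from 176 to 54.2 FPKM, and Cma1, from 18.0 to 6.86 FPKM, fell, and 3 were called over the list alone. That excess did not pass Fisher's exact test, with an adjusted p = 0.0591, and did so when the adjustment of the genes covered all rows, with an adjusted p = 0.0302 by the same exact test.

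Of 16 megakaryocyte and platelet markers, 2 rose. Among them Itgb3, the integrin beta-3 gene, went from 3.94 to 26.7 FPKM. With the p-values adjusted over the list alone, 3 were called, Gp9 among them. Itga2b, the integrin partner of Itgb3, was at 218 FPKM in hCALR cells and 210 FPKM in hCALR-del52 cells and was not called. Fisher's exact test gave the list an adjusted p = 0.105 for higher calls. Of 3 measured T and NK cell markers, from a list of 28, Cd3g rose, and the exact test gave an adjusted p = 0.186. None of 5 measured pro-B and pre-B cell markers, from a list of 28, was called, either over all genes or over the list alone. The same held for 4 measured fibroblast and stromal markers, from a list of 26. Most members of these lists were not measured, so that the lists say little about these cell types.

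In the list of 18 cytokine receptor and JAK-STAT components, 1 gene rose and Jak1 fell, and 2 were called over the list alone. The genes of the IL-3 receptor were not called. Il3ra was at 40.2 and 36.9 FPKM, Csf2rb at 438 and 263 FPKM and Csf2rb2 at 325 and 187 FPKM in hCALR and hCALR-del52 cells. Csf2rb and Csf2rb2 are near copies of each other and can share reads. Jak2 was at 28.6 and 29.8 FPKM, Stat5a at 24.7 and 29.0 FPKM and Stat5b at 21.2 and 18.7 FPKM, and none of these was called. Of 22 JAK-STAT5 target genes, Socs1, a feedback inhibitor of cytokine signalling, fell from 5.16 to 1.90 FPKM, and the kinase gene Pim2 fell from 20.2 to 8.38 FPKM. Both were called over the list alone, but the call of Pim2 ended when the adjustment covered all rows, with an adjusted p of 0.0973. Cish, at 22.3 and 15.2 FPKM, and Pim1, at 269 and 215 FPKM, were not called. Of 18 early and feedback genes of the ERK pathway, Fos rose from 1.41 to 4.99 FPKM and Ier2 from 46.6 to 84.9 FPKM, both also over the list alone. The call of Ier2 ended when the adjustment covered all rows, with an adjusted p of 0.0664. In Fisher's exact test, the excess of lower JAK-STAT5 targets had an adjusted p = 0.112 and that of higher ERK pathway genes an adjusted p = 0.110.

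Among stress response lists, calls were few. Of 28 genes of the unfolded protein response and ER chaperones, the transcription factor gene Xbp1 fell from 88.4 to 48.4 FPKM. That call ended when the adjustment covered all rows, with an adjusted p of 0.127, and no member was called over the list alone. The chaperone gene Hspa5 was at 222 and 171 FPKM and Ddit3, which encodes CHOP, at 33.3 and 26.4 FPKM, neither of them called. Of 24 targets of ATF4 and CHOP, Ddit4, an inhibitor of mTOR signalling, rose from 21.1 to 46.6 FPKM and was the 1 member called over the list alone. Of 20 p53 target genes, Btg2 rose from 7.03 to 13.01 FPKM, also over the list alone, but not when the adjustment covered all rows, with an adjusted p of 0.0757. Of 17 NF-kappaB target genes, the chemokine gene Ccl5 rose from 6.13 to 14.9 FPKM and the cytokine gene Il6 fell from 16.4 to 8.15 FPKM. There 3 were called over the list alone, and the call of Il6 ended when the adjustment covered all rows, with an adjusted p of 0.0973. Of 22 adhesion and migration receptors, the chemokine receptor gene Ccr1 fell from 6.28 to 1.80 FPKM, also over the list alone.

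No member was called, over all genes or over the list alone, among 29 genes of G2 and mitosis, 26 of S phase, 26 of glycolysis and hypoxia, 22 of cholesterol synthesis, 19 of class I antigen presentation, 31 cytosolic ribosomal proteins, 27 of calcium handling, 22 NRF2 targets, 17 heat shock genes and 13 BCL2 family genes. The values of several of these lists nevertheless lay to 1 side. Each list's median log2 ratio was set against 10000 random lists of the same size and expression, which describes these group values and is no test over replicates. Members of a list vary together, so that such a list lies outside the range of random lists more easily than a list of unrelated genes. Of 26 lists, 15 had a median outside the middle 95% of random lists, 7 above and 8 below, against 1.30 expected by chance for lists of unrelated genes.

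All 29 measured genes of G2 and mitosis had a ratio above 0, with a median of 0.31, above every random list. Cdc20, an activator of the anaphase-promoting complex, was at 98.2 FPKM in hCALR and 162 FPKM in hCALR-del52 cells, and Ccnb1, which encodes cyclin B1, at 36.8 and 50.8 FPKM. The medians of the erythroid (0.39), interferon (0.36) and p53 (0.30) lists also lay above every random list. Those of the ERK pathway (0.22), S phase (0.18) and cholesterol (0.17) lists were at the 99.98th, 99.98th and 99.99th percentile. The erythroid median rests in part on globin genes, and the 14 erythroid markers other than globins had a median of 0.17.

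Of 26 glycolysis and hypoxia genes, 25 had a ratio below 0, with a median of -0.28, below every random list. Pfkl, which encodes liver phosphofructokinase, was at 137 and 80.8 FPKM, and the glucose transporter gene Slc2a1 at 68.7 and 48.0 FPKM. The median of the unfolded protein response list was -0.23, with 26 of 28 members below 0, and that of the granulocyte list -1.16, both below every random list. Without Emr1, its 1 member on chromosome 17, the granulocyte median was -0.60, at the 0.01th percentile. The medians of the mast cell (-0.20), JAK-STAT5 target (-0.12), cytokine receptor (-0.13) and adhesion (-0.10) lists were at the 0.31th, 0.68th, 0.81th and 1.3th percentile. With a pseudocount of 0.1 the mast cell median was -0.32. The mean of the cytokine receptor list was 0.10, opposite in sign to its median.

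The class I antigen presentation list had a median of -0.36, below every random list. Its 11 members on chromosome 17, which include the H2 genes, Tap1, Tap2, Psmb8 and Psmb9, were all below 0 with a median of -0.49, while its 8 members elsewhere had a median of 0.01. Tap2, a subunit of the peptide transporter, was at 347 and 214 FPKM, and B2m, on chromosome 2, at 678 and 679 FPKM in hCALR and hCALR-del52 cells. The 513 measured genes of chromosome 17 had a median of -0.17, and the medians of the other 19 chromosomes with at least 50 genes lay between -0.04 and 0.02. Among the chromosome 17 genes, the 103 at 33 to 38 Mb, the H2 region, had a median of -0.25.

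**Figure D2:**
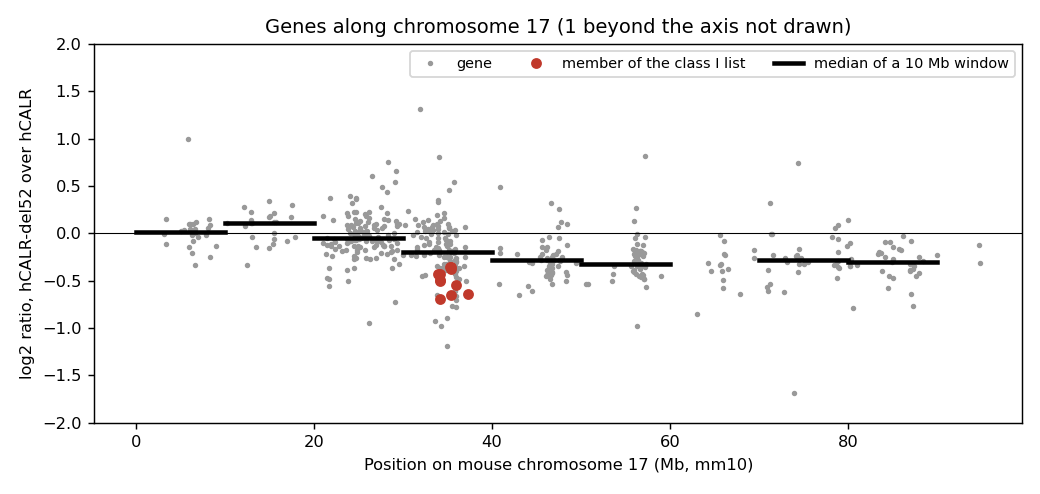
Log2 ratio of hCALR-del52 over hCALR for the genes of mouse chromosome 17 against their position in Mb (mm10). Grey points are genes, red points members of the class I list, and black bars medians of 10 Mb windows with at least 20 genes. The 185 genes before 30 Mb had a median of -0.01, and the 328 genes from 30 Mb on a median of -0.27, where 30 Mb was chosen after the values were seen.

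The other lists lay within the range of random lists. Their medians were 0.09 for ribosomal proteins (73.0th percentile), 0.07 for NF-kappaB targets (93.0th), 0.06 for megakaryocyte markers (83.7th), 0.04 for T and NK cell markers (67.99th), 0.03 for the BCL2 family (68.7th), 0.02 for pro-B markers (61.6th), -0.00081 for heat shock genes (40.1th), -0.0045 for NRF2 targets (39.8th), -0.02 for ATF4 and CHOP targets (29.2th), -0.04 for calcium handling (15.3th) and -0.13 for stromal markers (10.9th). The means of the pro-B list (-0.16), of the ATF4 and CHOP list (0.07) and of the heat shock list (0.01) had the opposite sign to the medians.

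**Figure D3:**
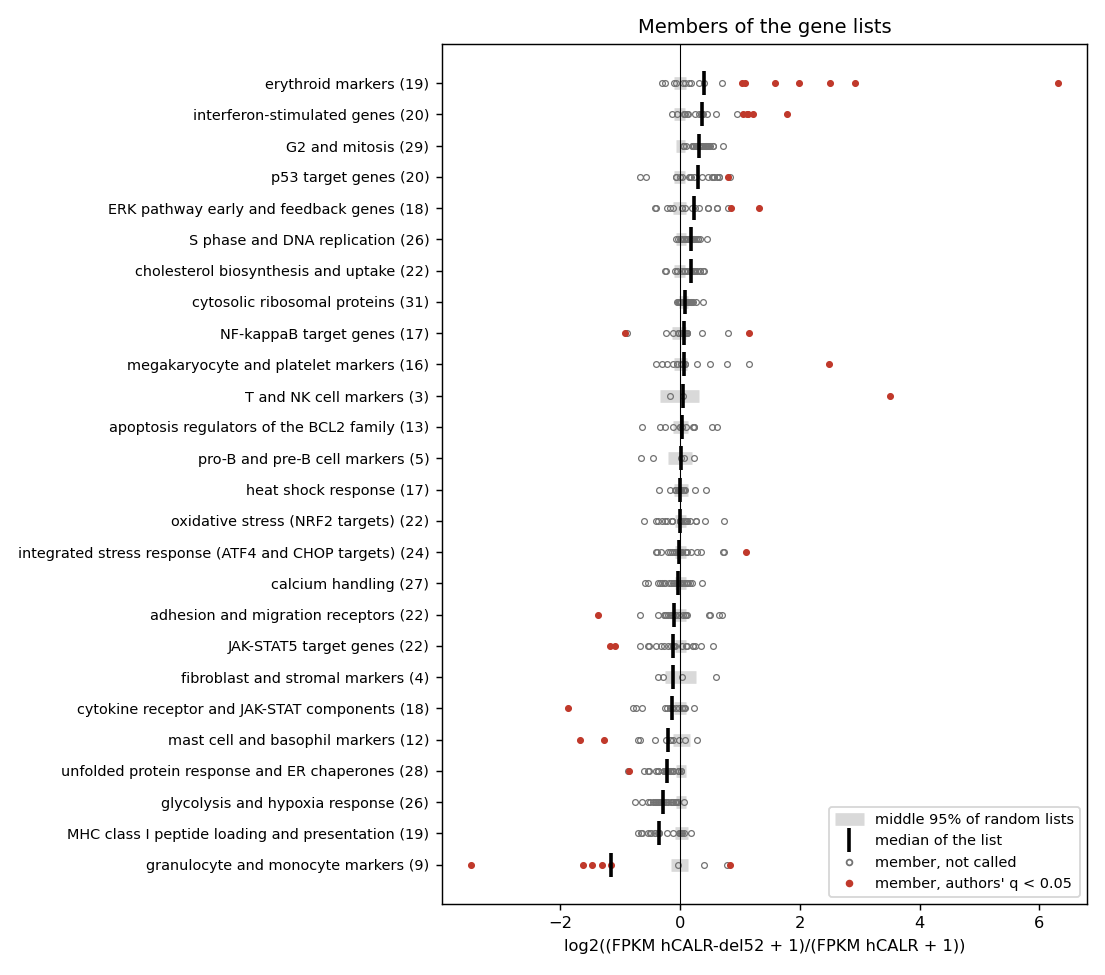
Log2((FPKM hCALR-del52 + 1)/(FPKM hCALR + 1)) of the measured members of 26 gene lists, with the number of measured members in parentheses. Points are genes, filled red where the authors' q is under 0.05, black bars are list medians, and grey bars span the middle 95% of random lists of the same size and expression. Genes not reported here are not drawn. The granulocyte and monocyte list has the lowest median, -1.16, and the erythroid list the highest, 0.39. Without globin genes the erythroid median was 0.17.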

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

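No paired analysis was possible because the table gives 1 value per group. For the same reason no replicate was left out, no replicate block or count model was fitted, no other split of the samples was tried, and what depth limits could not be assessed. The rows of single genes, the lists without chromosome 17 and the list tests with calls adjusted over all rows were chosen after seeing the data. Of 232 calls (110 higher, 122 lower), 159 passed a q of 0.01, of which 73 higher genes are fewer by over 1.5 times, since the threshold is stricter. Bonferroni adjustment left 0 calls, 0 higher and 0 lower, by construction. The smallest p in the authors' deposited table, 5e-05, times 12615 rows exceeds 0.05. An unadjusted p under 0.05 was found in 618 rows, against 631 expected with no change at all. However, 115 rows had the smallest p, far more than no change would give. Since rows had been removed from the table, the count under 0.05 does not measure how many genes changed. The minimum of 1 FPKM removes no row, so alone it tests nothing, and the planned new adjustment with it equals adjustment over all rows. That left 172 calls (80 higher, 92 lower), ending 60, 8 of them of genes named by the rule. The erythroid, interferon and granulocyte lists kept their excess of calls under every alternative run. With a minimum of 5 FPKM, and with a q of 0.01, 5 lists instead of 3 had an excess, the added lists being mast cell and megakaryocyte markers (the cause was not tested). List medians outside the random range kept their sign and stayed outside under each alternative run for them, except that the class I list turned from -0.36 to 0.0055 without chromosome 17, since its low members lie there. Centring moves the random lists by the same amount, so that it cannot bring a list into the range. With a minimum of 5 FPKM the stromal list, then of 3 genes, also lay outside, with a median of -0.29 at the 2.45th percentile. In size, the granulocyte median moved from -1.16 to -0.60 without chromosome 17 and the mast cell median from -0.20 to -0.32 with a pseudocount of 0.1. Calr moved from -0.3803 to -0.3806 with a pseudocount of 0.1 and to -0.3717 after centring. None of 108 recomputed ratios of named genes changed sign, but this was fixed in advance. A pseudocount cannot change a sign, and centring moved each ratio by less than the smallest of them, 0.056 for Jak2.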

Other observations

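Apart from the 10 Mb window test on chromosome 17, all tests in this part were chosen after the result was seen, and so were the genes named here. Further called genes lay outside the naming rule. The embryonic alpha-globin gene Hba-x rose from 1.10 to 8.42 FPKM, the lysophospholipid transporter gene Mfsd2b from 10.6 to 58.1 FPKM and the biliverdin reductase gene Blvrb from 54.2 to 118 FPKM. The inflammatory caspase genes Casp1, from 9.61 to 2.54 FPKM, and Casp4, from 11.997 to 3.04 FPKM, fell together. Pik3c2g, a lipid kinase gene, fell from 536 to 155 FPKM. Among troponin genes, Tnnt1 rose from 2.74 to 7.29 FPKM beside Tnni1, while Tnni3, in a row that carries 2 identifiers, fell from 15.6 to 5.98 FPKM, a call that ended when the adjustment covered all rows (adjusted p of 0.103).

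The table holds 7 rows for 5 T cell receptor beta variable segments, of which 4 rows were called lower and 0 higher, 3 of the 4 also when the adjustment covered all rows. Trbv17 and Trbv26 each have 1 called row and 1 row that was not called. Of the alpha segments, Trav18 rose from 0.309 to 2.17 FPKM, and Trav17 was at 6.69 and 24.7 FPKM without being called. The row of the gamma constant gene Tcrg-C1, which carries 2 identifiers at a locus shared by 7 rows, was at 20047 FPKM in hCALR and 830 FPKM in hCALR-del52 cells without being called, with p = 0.0895 in the authors' deposited table. Called genes stood beside called genes of the same direction 15 times, within 500 kb, among 8545 genes in genomic order. In 5 of these pairs both genes were globins, and without globin genes 9 pairs were left, where permuting the calls over genes gave 1.41 on average. Most of the pairs, such as Casp1 with Casp4 and S100a8 with S100a9, are neighbouring members of 1 gene family, which can be regulated together or share reads, so that their calls are not independent and the permutation does not test chance placement.

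Chromosome 17 had a median log2 ratio of -0.17 over 513 genes. Permuting chromosomes over genes gave no median as far from that of all genes (permutation p = 0.0001, the smallest possible). That p makes no allowance for the choice of chromosome 17 as the lowest of 20, and it treats neighbouring genes as independent. The permutation therefore does not exclude chance. Genes outside the H2 region (33 to 38 Mb) still had a median of -0.15, so this region alone does not account for the lower median of chromosome 17. A fall of class I presentation genes wherever they lie is argued against by a median of 0.0055 over the 8 members elsewhere. Those 8 are other genes than the 11 members on chromosome 17. The median of these 11, -0.49, was lower than that of all 103 genes at 33 to 38 Mb, -0.25. Whether they fell further than the region around them was not tested. A shift over most of the chromosome stays undecided, since 62.5% of its 10 Mb windows had a median below -0.05 (5 of 8, against 11.1% of windows elsewhere), and the 185 genes before 30 Mb had a median of -0.01. A lower copy number from 30 Mb on in some or all hCALR-del52 cells, or a higher one in hCALR cells, stays open, since no DNA was measured and the 30 Mb start was picked from these ratios: the medians there, -0.29 in the more and -0.26 in the less expressed of 328 genes, largely restate that choice, and an effect of hCALR-del52 itself was not tested.

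Of 19 measured erythroid markers, 8 were called higher in hCALR-del52 cells and 11 were not called. Reads shared between globin copies cannot account for the calls outside the globins, where 3 of 14 erythroid markers were called higher (Fisher's exact test, two-sided, p = 0.00029). Among these 3, the call of Rhd ended when the adjustment covered all rows, with an adjusted p of 0.0599. Whether shared reads account for the globin calls was not tested, and calls of other genes cannot decide it. Red cell precursors mixed into the hCALR-del52 cultures were not tested for, and the labels name only Ba/F3 cells. Of the 11 markers that were not called 7 had a ratio above 0 and 4 below, a split that does not decide the question. A response of the Ba/F3 cells to hCALR-del52 is also open and was not tested. Each construct was carried by its own transduced cells, and the labels name no separate transductions. Such a response therefore cannot be told apart from other differences between the lines.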
